A study of Mus musculus with 2 samples.

How the data were processed

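The series measured single-cell RNA of whole aorta from mice lacking apolipoprotein E (ApoE-/-), which were fed a high-fat diet (HFD) with or without the STAT5 inhibitor STAT5-in-1 (S5i). Per the labels' protocols, the diet held 21% fat and 0.20% cholesterol, S5i was given by mouth at 10 mg/kg in 5% DMSO, and HFD control mice received the vehicle. Aortas were digested with collagenase for 1 h at 37 °C, red cells were lysed, and cells pooled from 6 mice were fixed and frozen before the probe-based assay (10x Genomics Fixed RNA Profiling). Per the labels' protocols, viability was at least 70%, and the labels give mice of both sexes aged 8 to 12 weeks.

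The 2 GEO samples are 2 pools, each loaded on 1 chip from 4 libraries. Per the labels, pool 1 holds libraries 1 to 4, with the arms 4, 10 and 16 weeks of HFD and 4 weeks of S5i. Pool 2 holds libraries 5 to 8, with the arms S5i for 10 weeks, S5i for 16 weeks, 10 weeks of HFD with 6 weeks of S5i and 16 weeks of HFD with 12 weeks of S5i, the latter arms with S5i started 4 weeks into the diet. The titles write 14w where the treatment labels write 16 weeks. The labels do not pair a library with its arm, so contrasts between arms were not run, and libraries were numbered by their library names only. Of the 4 arms in pool 1, 1 received S5i, and all 4 arms in pool 2 did. The arms of 4 weeks lie in pool 1 only. Pool, chip, inhibitor and time on diet therefore cannot be told apart.

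Per the file headers, the deposited matrices hold UMI counts per gene and cell from Cell Ranger 8.0.1, for 19059 genes of the probe panel. Per the submitters' processing notes, the genome build was mm10 and R 4.4.1 with Seurat 5.1.0 was used. The authors' deposited marker tables give a log2 fold change of each cluster against the other cells, with a raw and an adjusted p-value whose test is not stated in the table. The authors' deposited lists of genes lower with S5i at 16 weeks give a log fold change, used here as a score because the base of the logarithm is not stated, and an adjusted p-value. Both lists hold only genes below -1 in that score with an adjusted p-value under 0.05, and no per-gene test was repeated. Cell barcodes of library 8 were not used here, so it was left out of the comparison of barcodes between libraries.

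Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, of 13 mitochondrial genes in the panel. Doublets were scored in each library with Scrublet in scanpy 1.11.5 at an expected rate of 0.1 and removed above a score of 0.25. That threshold was set after the scores were seen, because the automatic thresholds ran from 0.218 to 0.636 and called 0.252% to 10.8% of cells, against 4.13% to 8.97% at 0.25. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes chosen per library were scaled to a maximum of 10, and 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 1 followed, without integration across libraries. Scaling before the principal components was also chosen after a first look at the clusters. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 were used, and plots were drawn with matplotlib 3.10.9.

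Clusters were named from lists of cell type markers fixed before the data were examined. A marker's level in a cluster was set against the mean of its 2 highest levels over the clusters, with a floor of 20 CPM. A cluster was named when the mean level of its own markers was at least 0.5, at least 3 of them were found in at least 10% of its cells, and no other lineage's markers exceeded 0.3 of the own level. A cluster also went unnamed when over 90% of its cells came from 1 library, when its 10 leading genes held more markers of another class than of its own, or when it was shallow and held none of its own. These naming thresholds were chosen after the clusters were seen. Names are written with "-like" because they rest on RNA markers alone.

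UMIs of a class were summed per library and expressed as CPM, counts scaled to a class total of 1e6 UMIs. Libraries with under 100 cells of a class were left out of that class. Genes were compared between pools if they had a median of at least 10 CPM in 1 pool and at least 30 UMIs over the libraries. A gene was called apart between pools when every library of 1 pool lay above every library of the other and the log2 ratio of the pools' median CPM, with 1 CPM added, exceeded 1 in size. The libraries of a pool are different arms and not replicates, so no test was run between pools and no p-value was computed. Shares of cells carry exact Clopper-Pearson 95% intervals and levels of single genes exact Poisson intervals. Both cover counting error only. A count of 0 was read as at most 3 counts.

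The calling rule was tested on simulated data with the macrophage-like libraries' own depths and with each gene's spread taken from the 7 libraries. Of 50 genes changed by a log2 of 1, which is the threshold itself, 20 were called, and at a log2 of 1.5 all 50 were. Among 8696 unchanged genes, 19 were called. Changed genes were drawn from those well above the minimum of 10 CPM, and each changed alike in every library of a pool. The spread used there includes any difference between the pools, which raises the number of false calls.

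Genes named in the text follow a rule fixed before the data were examined. They are drawn, without printing each one, from the 12 higher and 12 lower genes with the largest ratios among those apart in macrophage-like cells, and 4 each way in smooth muscle-, fibroblast-, endothelial- and T cell-like cells. Named too are the 10 lowest genes of each deposited list, the 3 leading genes of each deposited marker cluster, members of the 15 fixed lists, and Apoe, Trem2, Gpnmb, Slamf9, Stat5a, Stat5b, Csf2ra, Csf2rb and Csf2. Genes named outside this rule are leading genes of clusters, 2 listed genes without overlap (Irf1 and Sh2d1b1) and 4 Y-linked genes, all chosen after the data were seen. The fixed lists cover STAT5 targets, foamy macrophage genes, lipid uptake and cholesterol efflux, cholesterol synthesis, resident macrophage genes, inflammatory genes, interferon response, antigen presentation, cell cycle, dissociation stress, smooth muscle contractile and modulated genes, extracellular matrix, endothelial activation and red cell RNA. Each list's median log2 ratio was placed among those of 10000 random lists of the same size matched on expression. Genes of a list move together, so that percentile describes these libraries and is no test. Positions of the named genes came from GENCODE vM21 on GRCm38 (mm10), matched by Ensembl ID for all 34 genes.

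Alternatives fixed before the data were examined were Leiden resolutions of 0.5 and 2, a minimum of 1000 UMIs, no filter on cells, doublets kept, 3000 variable genes, a pseudocount of 0.1 CPM, no filter on low values beyond 1 UMI, ratios of UMIs summed over the pool, TMM factors from edgeR 4.0.16 in R 4.3.3, and leaving out each library in turn. Alternatives added later were unscaled values, a naming threshold of 0.5 for other lineages, library 1 kept in the macrophage comparison, macrophage-like cells without the 10% with most contractile RNA, and macrophage-like cells without barcodes linked to a merged droplet.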

Results

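Single-cell RNA was measured in whole aorta of ApoE-/- mice, a strain that develops atherosclerotic plaque on a high-fat diet, after different times on the diet and with or without the STAT5 inhibitor S5i. STAT5a and STAT5b are transcription factors that carry signals of cytokines such as GM-CSF, the product of Csf2. The data form 2 pools of 4 libraries. Pool 1 holds the 3 diet arms without S5i and 1 arm with 4 weeks of S5i, and pool 2 holds 4 arms with S5i. Arms of 4 weeks lie in pool 1 only, so time on diet differs between the pools too. The libraries held 89219 barcodes, 41949 in pool 1 and 47270 in pool 2. Library totals ran from 35107782 UMIs in library 1 to 213270312 in library 8, and median UMIs per barcode from 1518.5 in library 1 to 7137 in library 5. After filtering, 78541 cells remained. Each arm is 1 library without a replicate, the arm of a library is not given, and all values below are per library, or as the median and range over the libraries of a pool.

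The aorta gave smooth muscle-like, fibroblast-like, endothelial-like, macrophage-like, dendritic, T, B, NK, plasma and neutrophil clusters, and a chondrocyte-like mural cluster led by Col2a1, Ibsp and Chad, genes of cartilage and bone matrix. The chondrocyte-like cells of libraries 2 and 3 (127 and 364 cells) were shallow, with medians of 2146 and 2031.5 UMIs. In the other libraries, with as few as 4 such cells, the medians ran from 16051.5 to 34342 UMIs. Of 65 clusters, 19 took a name from their markers. The 46 unnamed clusters held 37806 cells, 48.1% of those kept, and 37 of them carried markers of a second lineage. Smooth muscle-like cells made the largest named class by pool medians, with 20.3% of kept cells in pool 1 (range 7.02 to 35.3) and 16.4% in pool 2 (14.5 to 27.5). In libraries 2 and 3 fibroblast-like cells exceeded them, at 10.1% against 7.31% and 8.20% against 7.02%. The unnamed share was 50.2% to 66.8% in pool 1 and 33.5% to 42.2% in pool 2, without overlap, which 4 against 4 libraries give by chance for 2.86% of quantities. The median mitochondrial share of a library's barcodes did not overlap either, at 1.11% to 2.53% in pool 1 and 0.671% to 1.04% in pool 2, and 3.51% to 11.7% against 3.15% to 3.34% of barcodes were removed for it.

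**Figure D1:**
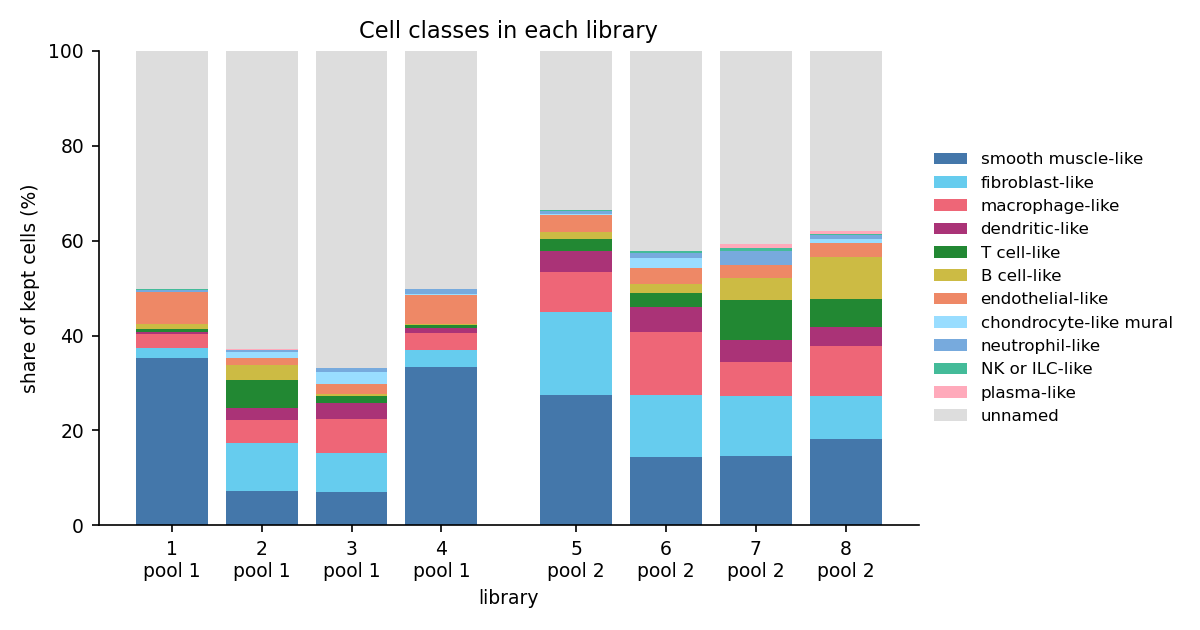
Stacked shares of kept cells (percent, vertical axis 0 to 100) of each cell class in libraries 1 to 8, by pool. The unnamed clusters took 33.5% to 66.8% of a library's cells, and all 4 libraries of pool 1 lay above all 4 of pool 2.

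The first comparison concerns which cells the diet and inhibitor arms held. Macrophage-like cells, the class that takes up lipid in plaque, made 2.75% (interval 2.22 to 3.37) of kept cells in library 1, 4.81% in library 2, 7.11% in library 3 and 3.63% in library 4. In pool 2 they made 8.35%, 13.3% (12.5 to 14.1), 7.09% and 10.65% in libraries 5 to 8. The median was 4.22% in pool 1 and 9.50% in pool 2, and libraries 3 and 7 overlapped. Fibroblast-like cells had a median of 5.88% (2.15 to 10.1) in pool 1 and 12.8% (8.96 to 17.5) in pool 2, and endothelial-like cells 4.06% (1.63 to 6.72) and 3.12% (2.59 to 3.64). Dendritic cells took 0.424% to 3.36% in pool 1 and 3.92% to 5.42% in pool 2 without overlap, T cells 0.589% to 6.01% and 2.60% to 8.25%, and B cells 0.353% to 3.00% and 1.40% to 8.91%. NK cells took 0.0107% to 0.118% and 0.162% to 0.483%, also without overlap, with as few as 1 cell in a library. These shares depend on the unnamed cells. As a share of named cells, macrophage-like cells ranged from 5.54% to 21.4% in pool 1 and from 12.0% to 23.0% in pool 2, with medians of 10.1% and 14.9%. Dendritic cells then overlapped too, at 0.852% to 10.1% and 6.32% to 9.38%, as did NK cells, at 0.0215% to 0.355% and 0.244% to 0.815%.

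Macrophage-like cells split into a resident cluster led by Cd163, Mrc1 and F13a1, a foamy cluster led by Cd5l, Mmp12, Gpnmb and Fabp5, and a small proliferating cluster. Foamy cells, named after their stored lipid, made 9.89% (4.62 to 17.9) of the macrophage-like cells of library 1 and 27.8%, 35.3% and 25.1% of those of libraries 2 to 4. They made 32.5%, 41.9%, 24.2% and 48.4% (45.9 to 50.9) of those of libraries 5 to 8. The pool medians were 26.4% and 37.2%, and the ranges overlapped. Proliferating cells made at most 4.77% of macrophage-like cells in any library.

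**Figure D2:**
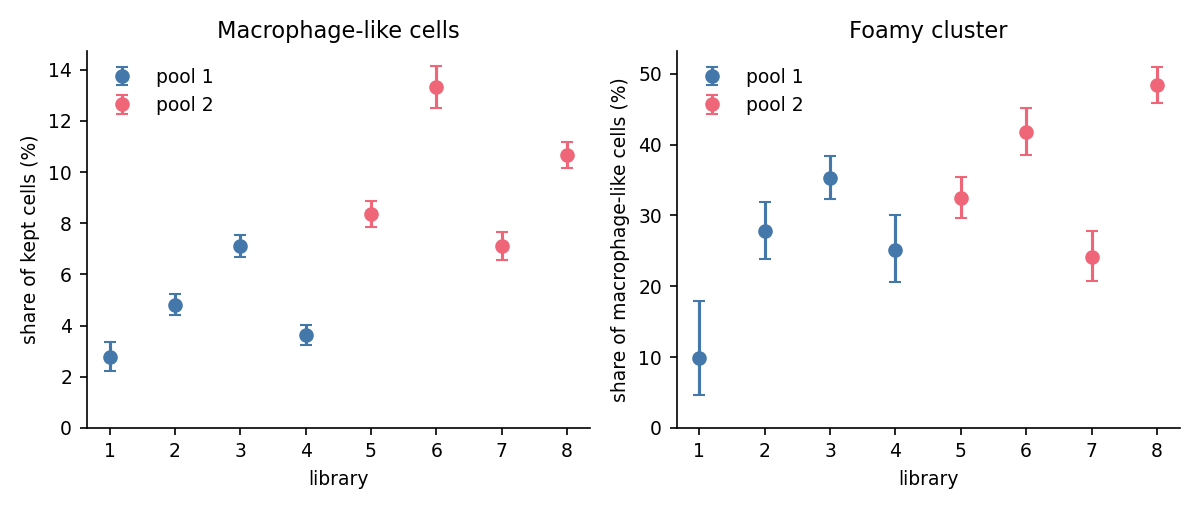
Macrophage-like cells as a share of kept cells, and foamy cells as a share of macrophage-like cells (percent, vertical axes from 0), in libraries 1 to 8, with exact 95% intervals for counting error. Foamy cells ran from 9.89% in library 1 to 48.4% in library 8, and the pools overlapped.

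Within the same library, foamy cells held more RNA for lipid handling and inflammation and less for antigen presentation and interferon response than resident cells. Tnf, an inflammatory cytokine, stood at a median of 524 CPM in foamy and 56.7 CPM in resident cells, and Cxcl2, a neutrophil attractant, at 2854 and 477 CPM. Abca1 and Abcg1, which export cholesterol, stood at 821 against 425 CPM and 481 against 129 CPM, and Soat1, which esterifies cholesterol for storage, at 300 against 85.2 CPM. H2-Ab1, a class II antigen presentation gene, stood at 712 against 7070 CPM, and Ifit3, an interferon-induced gene, at 8.78 against 122 CPM. Of 12 measured inflammatory genes, 10 were higher in foamy cells in each of 6 libraries (list median log2 1.16, libraries 0.53 to 1.48), and of 12 lipid uptake and efflux genes, 10 were higher and 1 lower (1.06). All 8 antigen presentation genes were lower in each library (-2.81), as were 10 of 11 interferon genes (-1.94) and 8 of 10 cholesterol synthesis genes (-0.50). Of 14 STAT5 targets, 7 were higher and 4 lower in every library, among them Pim1 at 570 against 188 CPM and Ccnd2 at 29.7 against 98.9 CPM. The clusters were made from expression, so genes that define them, such as the 16 foamy list genes (2.96) and the 10 resident list genes (-4.61), differ by construction. Markers of other cells were lower in foamy cells too, smooth muscle contractile genes at -1.28 (9 of 12 in each library) and extracellular matrix genes at -0.83 (10 of 12), and the foamy cluster had a median of 12823 UMIs per cell against 4053. Abcg1 and Cd36 are in both the foamy and the lipid list.

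Of the subsets in the authors' deposited table of mononuclear phagocyte markers, Trem2_Gpnmb matched the foamy cluster: 314 of 316 of its measured markers were higher in foamy than in resident cells. For the subset Pro/Anti-inflammatory Mac/Mono in the authors' deposited table the count was 240 of 297, and for Trem2_Slamf9 135 of 190. Of the resident subsets in the authors' deposited table, 20 of 442 markers of Resident CD209hi, 1 of 83 of Resident Lyve1+ and 8 of 22 of Resident proliferating were higher in foamy cells. IFNIC Mac markers of the authors' deposited table also lay with the resident cluster, with 1 of 179 higher in foamy cells. The authors' deposited table gives Jsrp1 the largest log2 fold change of Trem2_Gpnmb, 5.21, ahead of Cldn23 at 4.73 and Trim29 at 3.97. For Trem2_Slamf9 it gives Rims2 4.12, Stmn4 4.09 and Zfp618 3.55 in the authors' deposited table, and for Pro/Anti-inflammatory Mac/Mono Cxcl3 6.12, Proz 5.52 and Arg1 5.23. For Resident CD209hi the authors' deposited table lists Cd209f at 6.32, for IFNIC Mac Vnn3 at 3.06 and for Resident Lyve1+ Tceal6 at 4.59. Slamf9 itself stood at a median of 469 CPM in the resident and 221 CPM in the foamy cluster, and Trem2, a lipid-sensing receptor, at 127 and 334 CPM.

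Transcripts of the GM-CSF receptor were highest in myeloid cells. Csf2ra, its ligand-binding chain, had a median of 325 CPM in macrophage-like cells, 308 in dendritic cells and 451 in neutrophils, and 8.68 to 34.3 in smooth muscle-like, fibroblast-like, endothelial-like, T and B cells. Csf2rb, the signalling chain, stood at 140 CPM in macrophage-like, 293 in dendritic cells and 334 in neutrophils, and within macrophages at 177 CPM in the foamy and 74.0 in the resident cluster. It also reached 119 CPM in 1 library of endothelial-like cells (median 33.6) and 45.9 in 1 library of fibroblast-like cells (median 17.1). Csf2, the ligand, was sparse: its median was at most 0.924 CPM in each class but neutrophils, whose 6 UMIs gave 2.53 and 12.8 CPM in 2 libraries, and endothelial-like cells held 145 UMIs, with a median of 0 and up to 26.9 CPM in 1 library. Stat5a was highest in dendritic cells at 135 CPM and T cells at 87.6, against 25.6 in macrophage-like cells, and Stat5b stood at 161 CPM in T cells and 54.6 in macrophage-like cells. Cish, a direct STAT5 target, had 164 CPM in T cells, 51.4 in endothelial-like, 27.7 in dendritic and 4.45 in macrophage-like cells. Apoe, the gene targeted in these mice, stood at 15.5 to 21.5 CPM in the macrophage-like cells of libraries 2 to 8 and at 3.69 to 7.01 CPM over all kept cells of the 8 libraries. Its median was highest in endothelial-like cells, at 33.4 CPM (17.2 to 47.8). An untargeted control was not analysed here.

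The second comparison asked which macrophage genes set the inhibitor pool apart from the other. In macrophage-like cells, 3 genes of 8895 tested were apart between libraries 2 to 4 and libraries 5 to 8. Higher in pool 2 were Serpina3g, a serine protease inhibitor (10.2 against 1.22 CPM, log2 2.34), and Ccl8, a monocyte chemoattractant (285 against 132 CPM, log2 1.10). Gpr171, a G protein-coupled receptor, was lower (12.2 against 26.5 CPM, log2 -1.06). Serpina3g (ENSMUSG00000041481) lies on chromosome 12 at 104236245 to 104241939, Ccl8 (ENSMUSG00000009185) on chromosome 11 at 82115185 to 82116799 and Gpr171 (ENSMUSG00000050075) on chromosome 3 at 59096448 to 59101821, all GRCm38. These rest on 519, 12963 and 916 UMIs over the 7 libraries. The gap between the pools was narrow for Serpina3g, at 3.74 CPM in library 2 and 4.39 CPM in library 6. It was narrow for Gpr171 too, at 15.8 CPM in library 3 and 14.8 CPM in library 6. Of the 35 splits of these libraries into 3 and 4, 27 gave at least 3 genes apart, the real split among them. In all, 539 genes did not overlap between the pools, 6.06% against the 5.71% that chance gives for 3 against 4 libraries. The macrophage-like sums held 3766287 to 21251802 UMIs per library, and library 1 was left out for its 91 cells. The count was 41 without library 2, 25 without library 3, 10 without library 8, 8 without library 5 or 7 and 6 without library 4 or 6, and 5 with doublets kept and 7 with no filter on low values. Leaving out a library raises the share that chance gives, to 13.3% where 2 libraries of pool 1 meet 4 of pool 2. Trem2 stood at 200 against 272 CPM without overlap (log2 0.44), while Gpnmb (0.30), Slamf9 (-0.13), Stat5a (-0.21), Stat5b (-0.16), Csf2ra (0.11) and Csf2rb (-0.16) overlapped.

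Among the fixed lists, no member was apart between pools in macrophage-like cells (2, 6, 1 and 4 without libraries 2, 3, 6 and 8), and most lists lay near a log2 of 0. Cell cycle genes were lower in pool 2 than in libraries 2 to 4. Their median log2 was -0.44 over 9 genes, all below 0 and 6 of them without overlap. The list summed to 550 to 678 CPM in libraries 2 to 4 and 275 to 523 CPM in pool 2. Library 1, left out here for its few cells, held 80.3 CPM, below every library of pool 2. Proliferating cells had medians of 2.64% of macrophage-like cells in pool 1 (library 1 included) and 3.19% in pool 2, and the ranges overlapped. Mki67 stood at 152 against 111 CPM and Top2a at 122 against 81.6 CPM. Foamy genes had a median of 0.18 with 14 of 16 above 0, and Trem2 and Abcg1 without overlap, beside the higher foamy share. Lipid uptake and efflux genes stood at 0.14, with Abca1 (0.29), Abcg1 (0.33) and Nr1h3 (0.26), the receptor that induces both, without overlap. Antigen presentation genes stood at 0.35 (H2-Ab1 0.53, Cd74 0.40, overlapping) and interferon genes at 0.17, with Ifit3 (0.59) without overlap. STAT5 targets stood at -0.02, 7 of 14 above 0, with Socs3 at -0.14, Pim1 at 0.01 and Bcl6 at 0.32. Cholesterol synthesis was at -0.11, resident genes at -0.05, inflammatory genes at -0.05, dissociation stress at -0.13 and endothelial activation at -0.20, and with library 1 kept the last 2 turned to 0.00292 and 0.00904. Among random lists, the cell cycle list stood at percentile 0, antigen presentation and foamy genes at 100, interferon at 99.98, lipid genes at 99.81 and STAT5 targets at 32.0. Markers of other cells were less even. Extracellular matrix genes stood at -0.60, red cell RNA at -3.11, smooth muscle contractile genes at 0.03 and modulated genes at 0.02, and the summed contractile RNA in macrophage-like cells ran from 1034 CPM in library 6 to 9861 CPM in library 4.

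Within the resident cluster, 7 genes were apart between pools, among them the foamy genes Fabp5 and Gpnmb and the interferon gene Ifit2, all higher in pool 2, and 6.05% of genes did not overlap against 5.71% by chance. Gpnmb was low there, at a median of 52.6 CPM against 9096 CPM in the foamy cluster. The source of this RNA was not tested. The foamy list had a median log2 of 0.46 there, with 6 of 16 members higher without overlap, the interferon list 0.47 and antigen presentation 0.48. Within the foamy cluster, 19 genes were apart in 2 against 4 libraries, where 14.1% of genes did not overlap and chance gives 13.3%. The foamy list stood at -0.03 there. STAT5 targets had a median log2 of -0.11 in the resident cluster, with 4 of 14 above 0. In the foamy cluster their median was -0.07, with 5 of 13 above 0 and 1 member higher without overlap. Among random lists these medians stood at percentiles 1.67 and 1.355, against 32.0 in all macrophage-like cells.

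In the other classes the genes apart were mostly few. Smooth muscle-like cells had 3 of 8774, all higher in pool 2: H2-Aa (16.7 against 5.73 CPM, log2 1.39), Cd74 (42.0 against 15.7 CPM, 1.36) and Spp1 (50.0 against 20.3 CPM, 1.26), genes whose mean over the libraries was 3657, 8781 and 15943 CPM in macrophage-like cells. With unscaled values 0 smooth muscle genes were apart. The contractile list, with Acta2 and Myh11, had a median of 0.00 and the modulated list 0.08. Fibroblast-like cells had 6 of 9476, all higher: Cxcl13, a B cell attractant (81.8 against 18.9 CPM, log2 2.06), Hp (2.00), Serpina3n (2165 against 827 CPM, 1.39) and Serpina3m (1.24), the last 3 of the acute-phase type, and the interferon gene Rsad2 (1.10) were among them. Library 3 of pool 1 lay just below pool 2 for Cxcl13, at 31.8 against 32.0 CPM in library 5. The same held for Serpina3n, at 1985 against 1996 CPM in library 5, and Hp, at 155 against 158 CPM in library 8. Endothelial-like cells had 27 of 9597, with Nfasc (2.20), Mest (1.68), Nos1 (1.54) and Cmah (1.40) among the 6 higher and Hdc (-2.16), Slc28a2 (-1.54) and Cxcl9 (-1.47) among the 21 lower. Of these 21, 10 are mitochondrial transcripts, which were also higher in pool 1 over all barcodes. With doublets kept Hdc (0.21), Slc28a2 (0.37) and Cxcl9 (0.18) were higher in pool 2, as was Cxcl9 (0.43) without a filter on cells, and Mest (-0.00800) was lower at Leiden resolution 2. Non-overlapping genes made 5.09% in smooth muscle-like and 3.65% in endothelial-like cells, against 2.86% by chance, and 7.18% in fibroblast-like cells, against 5.71%. The endothelial count was 9 without library 1, 73 without library 2, 65 without library 3, 43 without library 7 and 51 without library 8, and 63 at resolution 2, 17 without a filter on cells and 47 with no filter on low values. With 1 of the 8 libraries left out, chance gives 5.71% of genes without overlap in place of 2.86%. The fibroblast count was 15, 40, 10, 10 and 11 without libraries 2, 3, 4, 6 and 8, and the smooth muscle count 8, 10, 5, 7 and 6 without libraries 2 to 6. With no filter on low values they were 18 and 10.

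T cells had 306 of 9471 genes apart in 2 against 4 libraries, 217 higher and 89 lower in pool 2, with 18.9% of genes not overlapping against 13.3% by chance. Lower were Trbv23, a T cell receptor segment (14.4 against 122 CPM, log2 -3.00), Comp (-2.17), Cfap74 (-1.93) and Zwilch (-1.85). Higher were Hdc (3.61), the natural killer receptor Ncr1 (28.3 against 2.37 CPM, 3.12), the antibody gene Igkc (2.89) and the chemokine receptor Ccr6 (47.5 against 6.78 CPM, 2.64). Hdc rests on 56 UMIs, with 0 CPM in library 3 and 3.05 CPM in library 8. With that 0 read as at most 3 counts, library 3 could lie above library 8, so the Hdc call and ratio are uncertain. The T cell class joined a mature cluster with Ccl5, Trac and Cd8b1 and a cluster with the thymocyte genes Rag1 and Dntt, of which 60.6% came from library 2, and that library made 1 of the 2 in pool 1. Without a filter on cells the count was 105, Ncr1 (-0.45) was lower and Comp (0.56) higher in pool 2, and from UMIs summed over the pool it was 467, and with no filter on low values 633.

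The third comparison followed the genes that the authors list as lower with S5i at 16 weeks. The Trem2_Gpnmb list in the authors' deposited table holds 40 genes, led by Cxcl10 at a log fold change of -7.59, Tnfsf9 at -3.65, Tnf at -3.19, Ccl4 at -2.69, Maff at -2.40, Egr1 at -2.27, Cxcl2 at -2.21, Itgb7 at -2.03, Phlda1 at -1.94 and Ccl3 at -1.93. They include 6 of the inflammatory list and 3 of the dissociation stress list. The Trem2_Slamf9 list in the authors' deposited table holds 9 genes: Cxcl10 at -2.04, Ccn1 at -1.37, Hspa1b at -1.16, Plbd1 at -1.11, Errfi1 at -1.10, Fcgr4 at -1.08, Ssh2 at -1.06, Mgl2 at -1.01 and Scimp at -1.003. Only Cxcl10 is in both. In the foamy cluster, 34 of the 40 had a lower median in pool 2, where 39.3% of all tested genes did, and the list's median log2 was -0.21. Tnf stood at 426 against 831 CPM and Egr1, an immediate early gene, at 434 against 624 CPM. They were among 4 listed genes without overlap, which chance gives for 13.3% of genes, and the others, chosen for this after their values were seen, were Irf1 (75.9 against 121 CPM) and Sh2d1b1 (85.6 against 96.1 CPM). Library 3 held the highest level of 27 of the 40 genes and library 5 the lowest of 28.

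**Figure D3:**
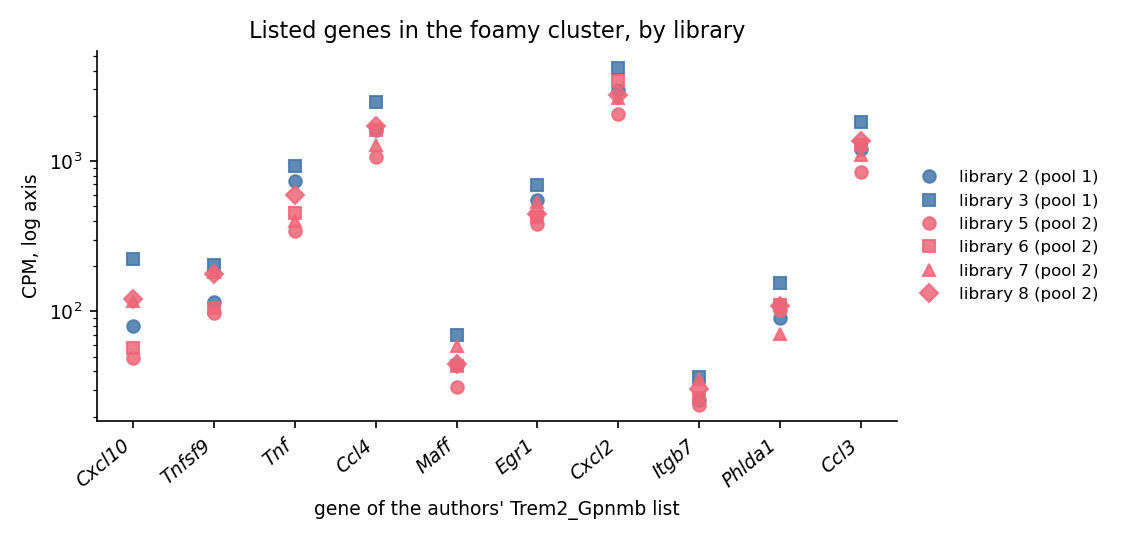
Levels (CPM, log axis) in the foamy cluster of the 10 genes with the lowest scores in the authors' Trem2_Gpnmb list, 1 point for each of libraries 2, 3, 5, 6, 7 and 8, coloured by pool. The median of Tnf was 831 CPM in pool 1 and 426 CPM in pool 2.

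In all macrophage-like cells, 21 of the 40 genes were lower in pool 2, 1 of them (Egr1) without overlap, where chance gives 5.71%. The latter count was 6 without library 2 and 2 without library 4, and 0 in 7 other alternatives: resolution 0.5, 1000 UMIs, doublets kept, unscaled values, TMM factors, library 1 kept, and without the 10% of cells with most contractile RNA. The former stood in a class where 55.8% of all tested genes were lower. In the resident cluster 15 of 40 were lower, in smooth muscle-like cells 8 of 25 measured, in fibroblast-like cells 13 of 28 and in endothelial-like cells 14 of 29. Of the 9 Trem2_Slamf9 genes, 8 were lower in macrophage-like cells, 1 without overlap (Errfi1), and 8 in the foamy cluster, 3 without overlap (Ccn1, Mgl2 and Scimp). That list belongs to the authors' Trem2_Slamf9 subset, to which no cluster here was matched, so both counts concern an unlike set of cells. The foamy count of 8 was 5 at 1000 UMIs. The count of 1 was 3 without library 4, 2 without library 2, 5 or 8, and 0 at resolution 2, at 1000 UMIs, without a filter on cells, with doublets kept, unscaled values or TMM factors, and without the 10% of cells with most contractile RNA. The authors chose both lists on these samples, so their direction is not independent evidence, and the arms they compare lie in different pools. The count of 34 was 20 at Leiden resolution 0.5, 17 with doublets kept and 21 with unscaled values. It was 20 without library 3 and 38 without library 2, where pool 1 is a single library, and 35.4% and 50.1% of all tested genes were then lower. In macrophage-like cells the count of 21 was 8 without a filter on cells, 13 with library 1 kept and 11 without library 3.

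Unnamed clusters shared droplets across libraries. A pool's 4 libraries are loaded together, so a droplet barcode can occur in more than 1 of them, and 31.4% to 57.2% of the kept barcodes of libraries 1 to 7 did so within their pool, against 3.41% to 4.84% across the pools. A barcode was called linked when its cluster and a cluster of another library of the pool shared at least 10 droplet barcodes and at least 10 times the number expected. Over all unnamed clusters of a library 16.5% to 41.1% of barcodes were linked, and over all named clusters 0% to 3.597%. Single clusters differed from this. Among named ones the chondrocyte-like cluster stood at 30.7% and 1 endothelial-like cluster at 16.6%, and among unnamed ones clusters 4 and 27 stood at 0%. No barcode of the smooth muscle-like clusters or of the foamy cluster was linked, and 1.55% of those of the resident cluster were. A cluster that holds a large share of a library can hardly reach 10 times the expected number. Smooth muscle-like cluster 0 made 5.29% (library 2) to 21.5% (library 1) of the kept cells of libraries 1 to 7. Of its barcodes 34.0% recurred within the pool, so its 0% is partly set by its size.

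**Figure D4:**
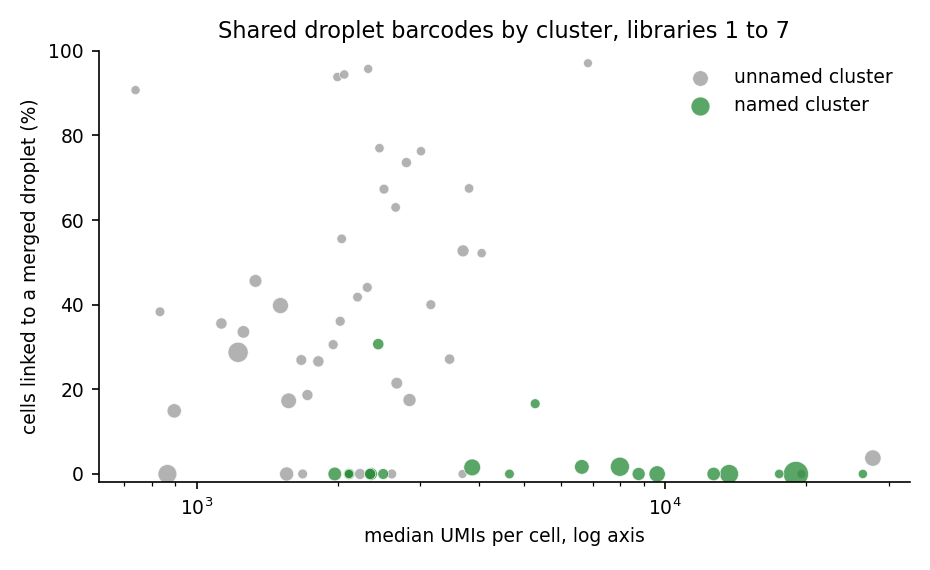
Share of a cluster's cells in libraries 1 to 7 that were linked (percent, vertical axis) against the cluster's median UMIs per cell (log axis), 1 point per named or unnamed cluster, with size by cell number. The highest named cluster was the chondrocyte-like one at 30.7%, and the highest unnamed one stood at 97.1%.

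Y-linked transcripts were nearly missing from library 2. Over all kept cells, Ddx3y, Eif2s3y, Kdm5d and Uty together gave 10 UMIs among 64544252 in library 2, 0.155 CPM (0.0743 to 0.285), and 83.8 to 215 CPM in the other libraries. Among smooth muscle-like cells with at least 20000 UMIs, 0 of 305 in library 2 held a Y-linked UMI, and 47.0% to 99.02% did in the other libraries, whose median depths of 25486 to 30574 UMIs were close to its 29680. Per the labels, both pools held males and females. The share ran from 0% in library 2 to 99.02% in library 5, so the mix of sexes may differ between libraries. No comparison of the pools was adjusted for it. The genes were chosen after the data were seen and were not used to assign arms.

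**Figure D5:**
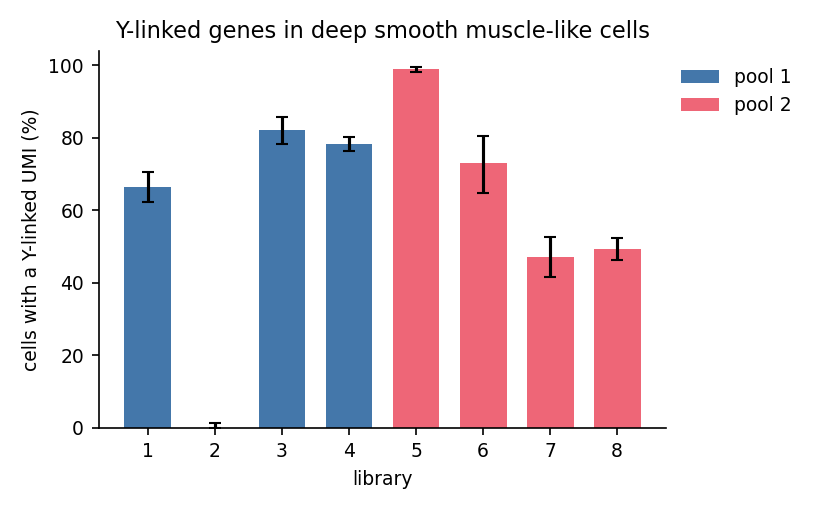
Share of smooth muscle-like cells with at least 20000 UMIs that held a UMI of Ddx3y, Eif2s3y, Kdm5d or Uty (percent, vertical axis from 0) in libraries 1 to 8, with exact 95% intervals for counting error. Library 2 stood at 0% and the other libraries at 47.0% to 99.02%.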

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

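Each value here stood far from those of the other libraries of its pool, which chance gives for about 1 in 20 of the groups looked at; of 66 groups, 4 did, or 6.06%. No explanation was tested, and the Y-linked genes were chosen only after the data were seen. Neutrophils made 2.94% of the kept cells of library 7, against 0.729% to 1.08% in the other libraries of pool 2. Plasma cells made 0.155% of library 2, against 0% to 0.0221% in the others of pool 1. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 0.155 CPM in library 2, against 136 to 161 CPM in the others of pool 1. The resident macrophage genes summed to 1130 CPM over all cells of library 1, against 1396 to 1450 CPM in the others of pool 1. In the macrophage-like cells alone library 1, with 91 such cells, was highest, at 4965 CPM against 2716 to 3751 CPM. The list was not confined to macrophage-like cells, with 1097 CPM in the smooth muscle-like cells of library 1.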

How the results depend on the processing

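The alternatives with unscaled values, a naming threshold of 0.5, library 1 kept, macrophage-like cells without the 10% with most contractile RNA, and macrophage-like cells without linked barcodes were chosen only after the data were seen. No paired analysis was possible because no number pairs a library of 1 pool with a library of the other.

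The macrophage-like share was 3.62% in pool 1 and 8.64% in pool 2 at Leiden resolution 2, 4.96% and 10.1% at 1000 UMIs, 4.82% and 10.3% without a filter on cells, and 3.47% and 8.15% with doublets kept. It was 10.4% in pool 2 with 3000 variable genes. In each of these settings the median was higher in pool 2. Leaving out 1 library gave 3.63% to 4.81% and 8.35% to 10.65%.

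With no filter on low values the genes apart were 7 in macrophage-, 10 in smooth muscle-, 18 in fibroblast-, 47 in endothelial- and 633 in T cell-like cells, with more genes tested. With doublets kept 5 macrophage genes were apart. With unscaled values 0 smooth muscle genes were. The endothelial count was 63 at resolution 2 and 17 without a filter on cells, and the T cell count 105 without that filter and 467 from summed UMIs. Leaving out 1 library gave 6 to 41 macrophage genes (41 without library 2), 2 to 10 smooth muscle genes (10 without library 3), 5 to 40 fibroblast genes (40 without library 3), 9 to 73 endothelial genes (9 without library 1, 73 without library 2), and 280 to 436 T cell genes. With fewer libraries, chance leaves more genes without overlap: 2.86% for 4 against 4 libraries, 5.71% for 3 against 4 and 13.3% for 2 against 4. These counts are therefore not directly comparable with the main ones.

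Of the Trem2_Gpnmb list, 8 genes were lower in pool 2 in macrophage-like cells without a filter on cells and 13 with library 1 kept. Its count without overlap was 0 at resolution 0.5, at 1000 UMIs, with doublets kept, unscaled values, TMM factors or library 1 kept, and without the 10% with most contractile RNA. In the foamy cluster its count was 20 at resolution 0.5, 17 with doublets kept and 21 with unscaled values. The count without overlap of the Trem2_Slamf9 list was 0 at resolution 2, at 1000 UMIs, without a filter on cells, with doublets kept, unscaled values or TMM factors, and without the 10% with most contractile RNA, and its foamy count was 5 at 1000 UMIs. Leaving out 1 library gave 11 to 31 (11 without library 3), 1 to 6 (6 without library 2) and, in the foamy cluster with a library of pool 2 left out, 31 to 35 for the first list, 6 to 9, 1 to 3 (3 without library 4) and, in that cluster, 8 to 9 for the other, and 0 to 6 fixed list members apart (6 without library 3, 4 without library 8).

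With library 1 kept, the median log2 of dissociation stress was 0.00292 and of endothelial activation 0.00904, both reversed. In endothelial-like cells Hdc (0.21), Slc28a2 (0.37) and Cxcl9 (0.18) reversed with doublets kept, Cxcl9 (0.43) without a filter on cells and Mest (-0.00800) at resolution 2. In T cell-like cells Comp (0.56) and Ncr1 (-0.45) reversed without a filter on cells. Of 413 values of named genes under the other alternatives, 48 were weaker and 7 reversed, and of 232 with 1 library left out, 13 were weaker. Of 105 list medians, 37 moved and 2 reversed, and 82 of 105 moved with 1 library left out. Counts of genes apart can rise where more genes are tested, and by chance where a library is left out. Other causes were not tested.

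Not run, for want of libraries with enough cells, was the T cell comparison with doublets kept and without library 2 or 3. In the foamy cluster, leaving out library 2 or 3 leaves 1 library in pool 1, and the counts were then 38 and 20 of 40 for the first list and 7 and 6 of 9 for the other. Of simulated changes of a log2 of 1.5 in macrophage-like cells, 50 of 50 were called. The changed genes lay well above the minimum of 10 CPM and changed alike in every library of a pool. Depth did not limit calls of that size for such genes. Changes in genes near 10 CPM or in some arms only were not simulated.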

Other observations

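The unnamed cluster 1, with 3629 cells and a median of 29327 UMIs, was led by Vcam1, Timp1, Cx3cl1, Lum and Lcn2 and made a median of 3.16% of kept cells in pool 1 and 5.85% in pool 2. An unnamed cluster of 328 cells with Il1rl1, Gata3 and Klrg1, genes of type 2 innate lymphoid cells, made 0.319% and 0.471%. Mast cell genes (Cma1, Mcpt4 and Cpa3) led 242 cells. A cluster with Tnf, Ccl3 and Ccl4 drew 66.1% of its cells from library 3. Red cell RNA over all kept cells was 363, 119, 10.8, 368, 44.3, 12.3, 23.3 and 11.5 CPM in libraries 1 to 8, although the label names cells without red blood cells.

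All tests below were chosen after the results were seen, except low depth, doublets with smooth muscle cells, depth of the macrophage-like cells and the count of other splits. A further 2 tests, on Cd74, H2-Aa and Spp1 in smooth muscle-like cells, were run and set aside after their results. In these cells 275 macrophage genes had a median log2 of 0.27, with a 95th percentile of 0.94, against 1.36, 1.39 and 1.26. Cd74, H2-Aa and Spp1 had been picked for being largest. Many of the 275 lay near or below 1 CPM there, such as Trem2 at 0.477 CPM, where the added 1 CPM pulls ratios towards 0. Cd74, H2-Aa and Spp1 stood at 30.1, 11.7 and 36.3 CPM, so the comparison cannot set them apart from other macrophage RNA.

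Clusters that mix markers of several lineages made 37 of the 46 unnamed clusters. A pair of intact named cells at their clusters' median depth would hold at least 2 times the median UMIs of the shallowest named cluster. Pairs with shallower cells or with cells of unnamed clusters are not bounded by this. Of the 36 with at least 20 cells in a library, 19 had fewer median UMIs than that in each such library. This argues against pairs of such named cells there. The other 17 reached that bound in at least 1 library, cluster 1 in all 8, where depth leaves pairs open. Of these 17, some lay under the bound in most libraries, such as cluster 8 in 6 of 8 libraries and cluster 29 in 4 of 5. In those libraries this argues against pairs of such named cells. A candidate explanation is a merged droplet with many barcodes and cells of several libraries: the linked share was at least 5.103 times higher in unnamed than in named clusters in each of 7 libraries, and cluster 13 of library 5 and cluster 10 of library 7 shared 178 droplet barcodes where 4.26 were expected. This sign was missing from some of the mixed clusters, with 0% linked in clusters 27 (3861 cells) and 4 (1690), among others, and 3.76% in cluster 1, so the explanation stays open there. Small clusters meet the rule for links more easily than large ones, so the ratio of 5.103 may partly reflect cluster size. Low depth cannot be told apart, since at 1000 UMIs mixed cells were still at least 3.04 times as frequent in unnamed clusters, but named clusters were selected for purity. No biological explanation was tested.

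In the foamy cluster, 34 of the 40 genes of the Trem2_Gpnmb list were lower in pool 2. A shift of these genes shared by the classes on the pool 2 chip is argued against. At most 48.3% of the measured listed genes were lower in smooth muscle-, fibroblast- or endothelial-like cells. Only 25, 28 and 29 of the 40 were measured there, and a chip effect on foamy cells alone stays open. Whether library 3 carries the pattern cannot be told apart, because only libraries 2 and 3 of pool 1 held enough foamy cells: against library 2 alone 50% of the listed genes were lower in pool 2 (35.4% of all tested genes), and against library 3 alone 95% (50.1%). Activation during digestion cannot be told apart, because the dissociation stress genes outside the list had a median of -0.0697 and go both ways. The inhibitor and time on diet, which the design confounds with the pool, stay open and untested.

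In macrophage-like cells, chance cannot be excluded for the 3 genes apart between pools: 27 of the 35 splits of the 7 libraries gave as many, and the highest other split gave 183. That split, libraries 2, 6 and 7 against the others, points to a structure of the libraries, and 181 of its 183 genes were lower in libraries 2, 6 and 7. Lower depth of their macrophage-like cells is argued against, since 2 of the other 4 libraries had median UMIs among theirs. RNA of mural cells and fibroblasts may explain it: 98.4% of the genes were at least 3 times higher in smooth muscle- or fibroblast-like cells, against 9.81% of all tested genes. Doublets with smooth muscle cells cannot be told apart. The 10% of macrophage-like cells ranked highest for contractile RNA held 62.3% to 85.7% of it, which the ranking partly builds in, on either side of the split, and 90.2% to 100% of the cells held a contractile UMI.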
